A study of Mus musculus with 2 samples.

How the data were processed

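The series comprises 2 two-colour oligonucleotide arrays of ureters dissected from male mouse embryos of the outbred NMRI stock at embryonic day 13.5. On each array 1 extract of Tbx2-GOF ureters and 1 extract of control ureters were hybridised together. Tbx2-GOF stands for a gain of function of the T-box transcription factor gene Tbx2: both genotypes carried a Tbx2 allele at the X-linked Hprt locus, and only the Tbx2-GOF embryos also carried cre at one Tbx18 allele. The control embryos had 2 normal Tbx18 alleles. RNA was amplified and labelled with AlexaFluor555 or AlexaFluor647, per the labels' protocols. The Tbx2-GOF extract carried AlexaFluor647 (red) on array 1, called replicate 1 in the labels, and AlexaFluor555 (green) on array 2, called replicate 2. The labels do not say whether the extracts of the 2 arrays came from separate embryos, so p-values measure only the spread between these 2 arrays, which may be technical. Both arrays lay on 1 slide and were scanned on 1 day, so there was no slide or scan batch to test; array and dye orientation cannot be separated.

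Scanner files were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The mean spot signals and median local backgrounds are intensity values as scanned, without normalization, per the file headers. The processed signals are intensity values that the software background-subtracted, detrended and dye-normalized with a linear and a LOWESS step, per the file headers. The software's log ratio is the log10 of red over green, per the file headers. Flags for spots well above background, saturated or outlying were set by the software. The deposited series value table holds a signed linear fold ratio whose scale, centring and direction were not stated; they were worked out from the values. No value lay between -1 and 1, the median was 1 on both arrays, and 31.5% and 31.1% of probes were exactly 1. Positive values were Tbx2-GOF over control: among probes above background in both channels, 99.2% and 98.8% matched the software's log ratio, turned by the labelled dyes, within 0.01 on the log10 scale. No further centring step was apparent from that match. How the table's values of exactly 1 were set is not given in the sources used here.

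Each array held 43020 spots for 39429 probes, and 1377 control spots besides. Of the probes 399 had 10 spots and the others 1. Feature Extraction flagged 209 spots on array 1 and 391 on array 2 as outliers, and no probe was saturated. The median green signal was 348 and 382 and the median red signal 452 and 449 on arrays 1 and 2, over median backgrounds of 28 and 28 in green and 94 and 87.5 in red. Precision is limited by the number of arrays.

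The main log2 ratios were computed here from the intensity values with limma 3.58.1 in R 4.3.3: normexp background correction with an offset of 50, then loess within each array with a span of 0.3 and with control spots and flagged spots at weight 0, and no scaling between arrays. Ratios were turned so that positive log2 values mean higher in Tbx2-GOF; a dye effect shared by the 2 arrays cancels in their mean. Control and flagged spots were left out and spots of 1 probe averaged. A probe was kept where the Tbx2-GOF channel or the control channel was well above background on both arrays, which kept 26471 probes and left out 12958. For each gene the kept probe with the highest mean log2 intensity was used; 4498 genes had more than 1 kept probe, and none of the named genes had a kept probe of opposite sign. Gene symbols were updated through RefSeq accessions of the mouse GRCm38.p6 assembly table, which matched 26412 probes (67.0%); the others kept the name in the scanner file. Probe coordinates are those of the scanner files, on mm9, counted from 1. No genome was used here, so exon and UTR positions of probes are not given.

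Each of the 21097 genes was tested with lmFit and eBayes (1 residual degree of freedom, an estimated 6.36 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment at 0.05. "Rose" and "fell" are used for genes past this threshold and, for gene lists, for those past the list test. A second, untested count took genes at least 1.5-fold apart on both arrays in the same direction, set beside those in opposite directions, the direction a dye effect takes. Where 1 group's channel was not well above background on either array, the ratio is given as "at least", against the higher of the lowest signal well above background and the probe's own signal, after loess and Aquantile normalization of single channels. Such a bound is open to dye bias on single arrays.

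Before the data were examined, 27 gene lists were fixed for signalling pathways, ureteric cell types, other tissues and dissection stress. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; list medians were also set against 10000 random lists matched on intensity. The list of cyclin-dependent kinase inhibitors and reported TBX2 targets was drawn up from knowledge of work on this gene and this organ, and some members may have been chosen by the study on these samples. The named genes were also fixed by a rule beforehand: Tbx2, Tbx3 and Tbx18; the 12 genes with the largest rise and the 12 with the largest fall among those past the test; and from each list up to 4 measured members with the smallest unadjusted p. This rule gave 122 genes. A further 7 lists were drawn up after the leading genes had been seen, without those genes. Genes without a symbol were counted, not named.

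The steps were tested on simulated data with 21097 genes on 2 dye-swapped arrays. Of 67 genes changed 1.5-fold 19.4% were recovered, of 67 changed 2-fold 82.1%, and of 66 changed 4-fold 98.5%; of the 165 calls 25 were false and another 7 were among 20 genes raised by 0.6 on the log2 scale for the list test. In 50 further repeats, gene-level ratios drawn from the fitted prior went straight into the fit, without background, dye bias, loess or probe choice. Among these the median share of false calls was 6.53% and the highest 35.0%, above the nominal 5%. Those shares cover the fit alone, not the steps before it. Alternatives listed beforehand were no background correction, an offset of 0, the software's processed signals, median centring in place of loess, scaling between arrays, no filter on dim probes, a filter on both channels of both arrays, the mean of a gene's probes, eBayes with trend and robust estimation, a separate-channel model, the series value table, other fold thresholds, each array alone, and for gene lists an estimated correlation and ranks.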

Results

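The transcriptome of the ureter was compared between Tbx2-GOF and control embryos at E13.5, when the mesenchyme around the ureteric epithelium has not yet formed contractile smooth muscle. The question set by the design was which transcripts change when the T-box repressor TBX2 is expressed from the Hprt locus in cells with a history of Tbx18 expression. There were 2 arrays with the dyes swapped, each holding 1 Tbx2-GOF and 1 control extract, so n = 2 for every mean below. The Tbx2-GOF channel was well above background for 66.7% and 72.9% of probes on arrays 1 and 2, and the control channel for 70.5% and 66.6%. Values are log2 ratios of Tbx2-GOF over control, as mean ± SD of the 2 arrays, with limma's adjusted p.

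Tbx2 itself, measured by 1 probe on chromosome 11 (mm9, 85655391 to 85655450), had a log2 ratio of 0.30 ± 0.37, with 0.04 on array 1 and 0.56 on array 2 (adjusted p = 0.711). Whether this probe lies in the part of Tbx2 that the Hprt allele carries could not be settled from the files, so it checks nothing about the labels. Tbx3, its closest relative, was at 0.18 ± 0.30 (adjusted p = 0.925). Tbx18, 1 allele of which carries cre in the Tbx2-GOF embryos, was lower on both arrays, at -0.31 and -0.59 (chromosome 9, 87599514 to 87599573), and did not pass the test (adjusted p = 0.266). Of the 10 measured genes of the T-box list, 0 passed the test over all genes and 4 did when adjusted over the list alone, 2 upward and 2 downward. The list median was 0.13 with a mean of 0.00, and the list did not pass camera (adjusted p = 0.614).

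In Tbx2-GOF ureters 76 genes rose and 59 fell, 135 of the 21097 genes tested; 66 and 55 of these had symbols. The largest rise was that of Akr1b7, an aldo-keto reductase abundant in adrenal cortex and vas deferens, at 3.27 ± 0.59 (9.65-fold, adjusted p = 0.00516, chromosome 6, 34372905 to 34372964). Next came Six2, the transcription factor that keeps nephron progenitors undifferentiated, at 1.85 ± 0.05 (3.62-fold, adjusted p = 0.00624, chromosome 17, 86083634 to 86083693). Gdnf, the RET ligand that drives outgrowth of the ureteric bud, rose by 1.53 ± 0.16. The others of the 12 largest rises were Lrriq1 at 1.58, Vgf at 1.58, Scg2 at 1.57, Fabp7, a fatty acid-binding protein of glial precursors, at 1.57, the neighbouring genes Higd1c (1.49) and Methig1 (1.35), Dpp10 at 1.44, the homeobox gene Uncx at 1.35 and Th, the rate-limiting enzyme of catecholamine synthesis, at 1.34. Uncx was at 1.98 with the software's processed signals and in the series value table.

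Farthest down was Afp, alpha-fetoprotein, which fell by 2.95 on the log2 scale (7.74-fold, SD 0.29, adjusted p = 0.00241, chromosome 5, 90937781 to 90937840). Alb, albumin, was at -2.15, Serpina6, corticosteroid-binding globulin, also at -2.15, and Tceal7 at -1.94. Ahsg, a foetal serum glycoprotein, was at -1.86 and Mstn, the growth inhibitor myostatin, at -1.76, each with the Tbx2-GOF channel well above background on 1 of the 2 arrays. The sizes of these falls depended on the processing. Over the alternatives Ahsg ranged from -3.02 to -1.75, Mstn from -2.89 to -1.73, Afp from -3.52 to -2.92 and Alb from -2.59 to -2.12. Serpina6 was at -2.84 with processed signals and in the series value table. Epyc (-1.66), Chrna1, a subunit of the muscle acetylcholine receptor (-1.66), Acta1, skeletal actin (-1.55), Angptl7 (-1.53), Cox6a2 (-1.49) and the transcription factor gene Klf4 (-1.47) completed the 12. Among these, Chrna1 ranged from -2.01 to -1.27 over the alternatives, Epyc from -1.97 to -1.63, Angptl7 from -1.86 to -1.48 and Cox6a2 from -1.87 to -1.45. Of the 12, Tceal7, Mstn, Chrna1, Acta1 and Cox6a2 were farther down on array 1 than on array 2, as was the skeletal muscle list below. The others of the 12 were farther down on array 2. For the leading rises and falls alike, a response of the ureter was not separated from other tissue in the extracts.

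The number of calls depended on the processing. With limma, 1970 genes had an unadjusted p under 0.05, yet the software's processed signals, median centring and the series value table each called 0 genes at the adjusted threshold (2064, 1219 and 2060 at the unadjusted one), and a separate-channel model called 4.

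Across genes the ratios of the 2 arrays correlated weakly, with Pearson's r = 0.308 and Spearman's rho = 0.125. Over all genes, 51.2% had the same sign on both arrays. Genes are not independent replicates. At least 1.5-fold on both arrays, 174 genes were higher and 115 lower in Tbx2-GOF, 289 in the same direction, against 22 in opposite directions. At 2-fold there were 33 and 24, against 6. Akr1b7, Six2, Gdnf, Afp and Alb were beyond 2-fold on both arrays, and each of the 135 called genes was beyond 1.5-fold on both. The test itself favours genes whose arrays agree, so this share of the called genes is not separate evidence. With the ratios not turned by dye, 0 genes passed limma's test at an adjusted p under 0.05. With median centring in place of loess, r was 0.0502 and genes at least 1.5-fold apart numbered 280 in the same direction and 295 in opposite directions.

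**Figure D1:**
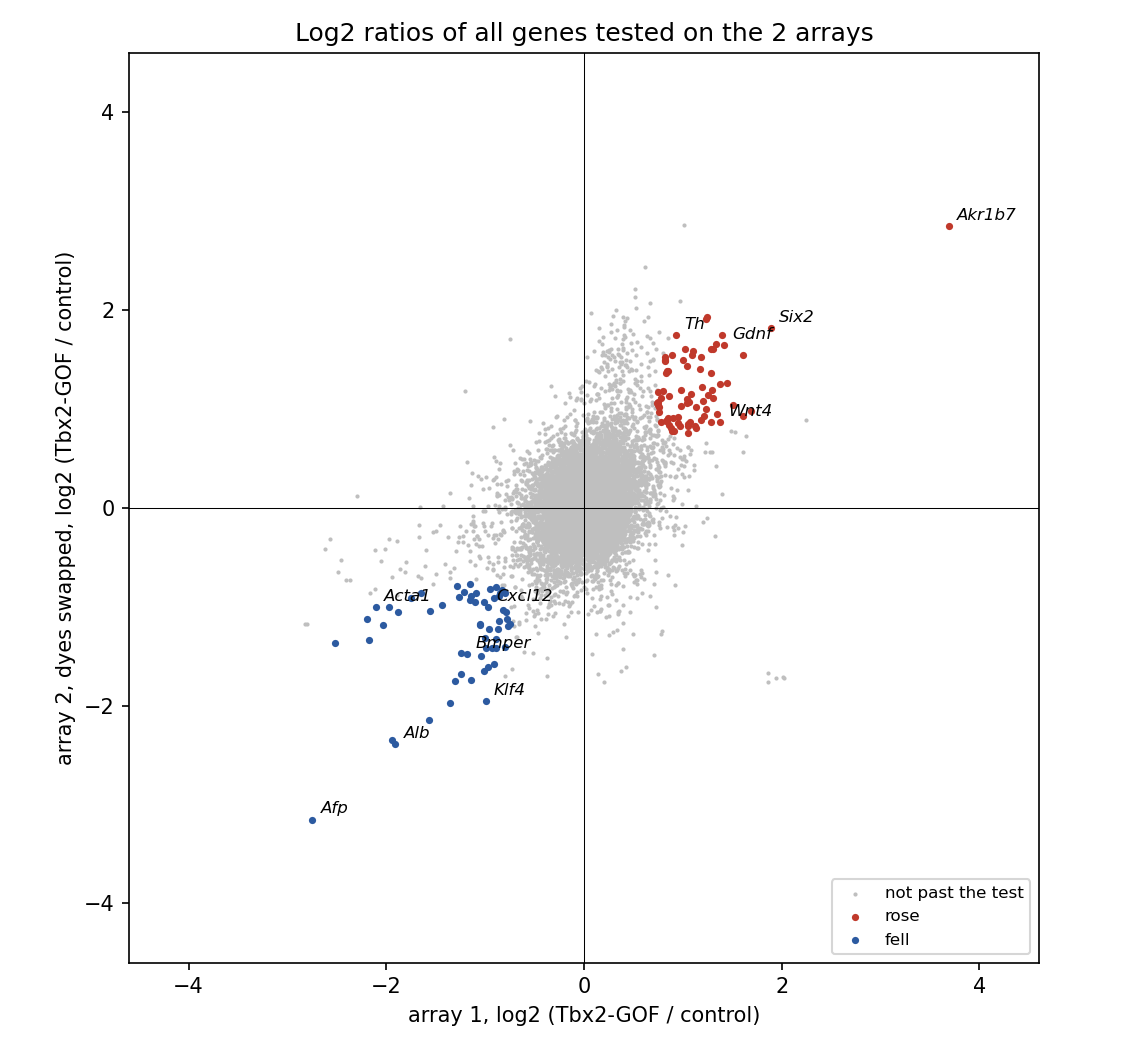
Log2 ratio of Tbx2-GOF over control on array 1 (x axis) and on array 2 with swapped dyes (y axis) for each of the 21097 genes tested; red and blue points are the 76 genes that rose and the 59 that fell, and grey points did not pass the test. The called genes lie in the upper right and lower left, with Akr1b7 and Afp farthest out.

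Lists of secreted antagonists and of reported TBX2 targets were lower by camera at the preset correlation. In the list of cyclin-dependent kinase inhibitors and reported TBX2 targets, 3 of 17 measured genes fell, 0 rose and 14 did not pass; 9 were lower when adjusted over the list alone. Bmper, an extracellular regulator of BMP signalling, was at -1.33 ± 0.21 (adjusted p = 0.0203, chromosome 9, 23289301 to 23289360), Shisa2, which holds WNT and FGF receptors back in the cell, at -0.86 and -1.15 on the 2 arrays (0.0379), and the chemokine gene Cxcl12 at -0.99 ± 0.02 (0.0319). Some of these genes may have been picked by the study on these samples, so neither the list's direction nor the count over the list alone is independent evidence. The list's median was -0.45 (-0.18 on array 1 and -0.56 on array 2), and it fell by camera at the preset correlation (adjusted p = 1.50e-08; adjusted p = 0.580 with an estimated correlation). The WNT antagonist list, which shares Shisa2, Dkk2, Frzb and Shisa3 with it, fell too, with a median of -0.40 (adjusted p = 3.47e-05; adjusted p = 0.580 with an estimated correlation) and 1 of 16 members called, or 8 lower and 1 higher when adjusted over the list alone. Dkk2 (-0.73), Frzb (-0.91) and Sfrp2 (-0.61) were lower on both arrays without passing the test (adjusted p = 0.0723, 0.0664 and 0.116). In the list of BMP and TGFB antagonists Bmper alone passed, and the median was -0.13 (camera adjusted p = 0.0307; adjusted p = 0.580 with an estimated correlation). That call was also lost with offset 0, processed signals, median centring, the series value table and ranks, at adjusted p from 0.0554 to 0.0675.

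WNT ligands rose as a list, with a median of 0.27 (camera adjusted p = 0.00605; adjusted p = 0.580 with an estimated correlation and 0.135 on ranks). The median was 0.31 on array 1 and 0.12 on array 2. Of the members, 2 of 13 members passed, and over the list alone 5 were higher and 2 lower. Rspo1, a secreted enhancer of WNT signalling, rose by 1.21 ± 0.13 (adjusted p = 0.0237) and Wnt4 by 1.12 ± 0.36 (0.0398). Wnt5a was at 0.77 and Wnt6 at 0.63 (adjusted p = 0.0691 and 0.134). The list of canonical WNT targets had a median of 0.15 (camera adjusted p = 0.0198; adjusted p = 0.580 with an estimated correlation) with 0 of 14 members past the test over all genes and 3 higher and 1 lower over the list alone; Sp5 was at 0.68 and Lgr5 at 0.60, whereas Twist1 was at -0.63. The Notch list, with Dll1 at 0.59 and Heyl at 0.69, had a median of 0.24, with 0.32 on array 1 and 0.11 on array 2 (adjusted p = 4.96e-04; adjusted p = 0.580 with an estimated correlation). None of its 13 members passed the test over all genes, and 2 were higher over the list alone.

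Single genes of other signalling lists passed the test while their lists did not. Cyp26b1, which degrades retinoic acid, rose by 0.94 ± 0.02 and Ecm1, a secreted matrix protein, by 0.85 ± 0.01 (adjusted p = 0.0379 and 0.0458). Aldh1a2 and Aldh1a3, which make retinoic acid, were at 0.71 and 0.70 (0.101 and 0.0858). The retinoic acid list had a median of 0.02, 2 of 16 members called, and over the list alone 4 higher and 2 lower (camera adjusted p = 0.323). Of 10 chemokine genes 3 fell, over all genes and over the list alone: Cxcl12, its scavenging receptor gene Ackr3 (-0.83 ± 0.04) and Ccl7 (-0.83 ± 0.00). The chemokine median was 0.07 while its mean was -0.18 and camera pointed down (adjusted p = 0.0894). Fgf7, a mesenchymal growth factor for epithelia, fell by 0.95 ± 0.24 on the log2 scale (adjusted p = 0.0449), the 1 call among 11 genes of the FGF list (median 0.09, camera adjusted p = 0.533; 1 higher and 2 lower over the list alone); Etv4, a transcription factor downstream of FGF receptors, was at 0.73 (0.0698). Neither BMP ligands and targets (median 0.04, adjusted p = 0.4997) nor the hedgehog list (-0.14, 0.296) had a member past the test over all genes or over the list alone.

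**Figure D2:**
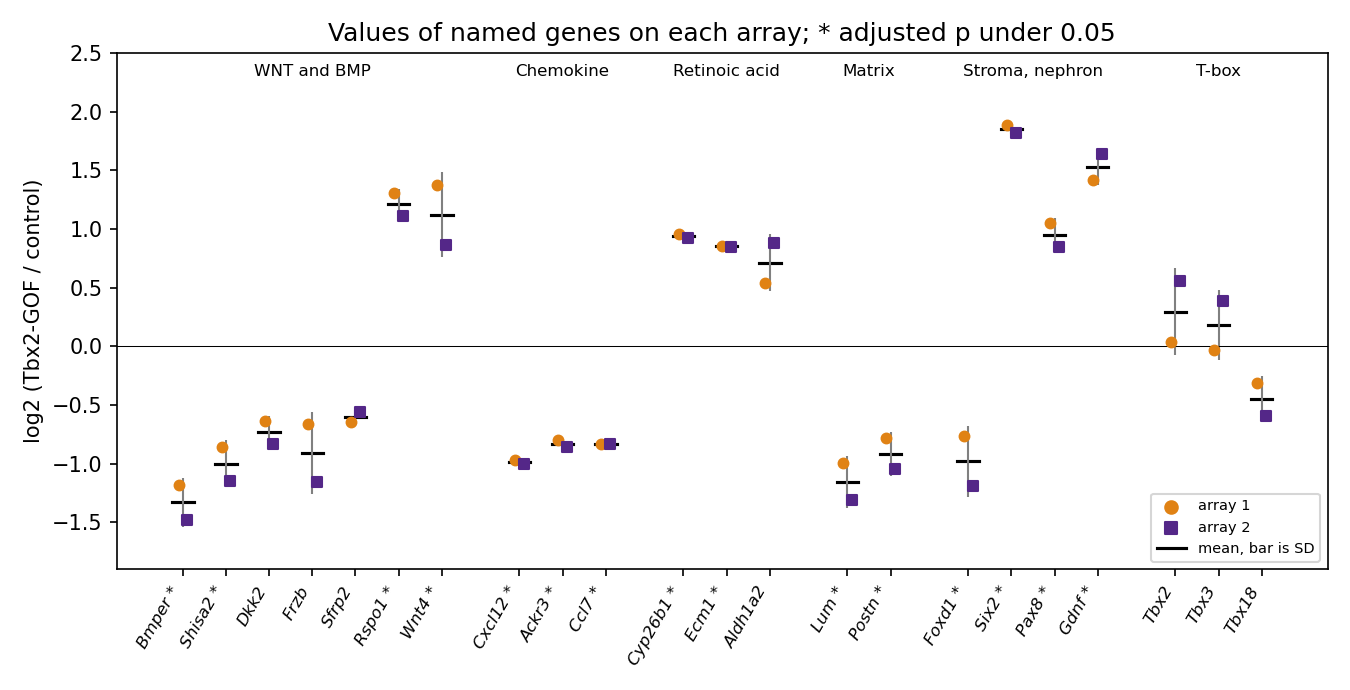
Log2 ratio of Tbx2-GOF over control (y axis) of named genes (x axis) on array 1 (circles) and array 2 (squares), with the mean (black line) and SD of the 2 arrays (grey bar); an asterisk marks an adjusted p under 0.05. Bmper was at -1.18 and -1.48 and Six2 at 1.89 and 1.82 on the 2 arrays, while Tbx2 was at 0.04 and 0.56.

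The fibroblast and adventitia list fell, with a median of -0.52 (camera adjusted p = 1.50e-08; 0.580 with an estimated correlation). Of its 15 members 2 fell and 13 did not pass, and over the list alone 8 were lower and 1 higher. Lum, the collagen-binding proteoglycan lumican, was at -1.16 ± 0.22 (adjusted p = 0.0278) and Postn, periostin, at -0.92 ± 0.19 (0.0449), whereas Aldh1a2, the list's 1 higher member, was at 0.71. Among 19 transcription factors of the ureteric mesenchyme Foxd1, a marker of stromal progenitors, fell by 0.98 ± 0.30 on the log2 scale (0.0471), the 1 call also over the list alone. That list had a median of -0.15 (-0.28 on array 1 and -0.01 on array 2; camera adjusted p = 0.0624); it passed camera with median centring, scaling and no dim filter (adjusted p = 0.0487, 0.0382 and 0.0415).

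Smooth muscle genes had a median of 0.03 (camera adjusted p = 0.614), and 1 of 17 passed, also over the list alone: Synpo2, an actin-binding protein, rose by 0.95 ± 0.23. Its other kept probes, which are dimmer, were at 0.04 and 0.31, and with the mean of its probes Synpo2 was at 0.44 and not past the test (adjusted p = 0.241). The median of 27 extracellular matrix genes was -0.01 with a mean of 0.02 (0.830), with 0 called and 1 higher over the list alone; camera pointed up, and down on ranks and with median centring. Col4a1 was at 0.78 ± 0.07 (adjusted p = 0.0584). The 23 cell cycle genes had a median of -0.02 (0.614), with 0 past either threshold. In the urothelium list 1 of 23 genes fell, Upk3a, a uroplakin, at -0.86 ± 0.01 (0.0450), while Upk2 was at 0.84 (1.70 with processed signals) and Gata3 at 0.73 (0.0715 and 0.0728); over the list alone 2 were higher and 1 lower, and the median was 0.13 (camera adjusted p = 0.108).

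Of the lists for other cell types and tissues, 5 passed camera at the preset correlation. The nephron and collecting duct list rose, with a median of 0.53 (camera adjusted p = 4.67e-08; adjusted p = 0.580 with an estimated correlation); Six2 and Pax8 (0.95 ± 0.14, adjusted p = 0.0398) were called among 10 measured genes, and 6 were higher over the list alone. Ret, the receptor gene for GDNF, was at 1.25 with 0.61 and 1.89 on the 2 arrays (0.1204). The neural and Schwann list rose, with a median of 0.96 (adjusted p = 1.55e-15; adjusted p = 0.580 with an estimated correlation), 2 of 15 members called (Fabp7 and Th) and 12 higher over the list alone; its medians on arrays 1 and 2 were 0.48 and 1.66. The skeletal muscle list fell, with a median of -1.19 (adjusted p = 3.45e-14; adjusted p = 0.580 with an estimated correlation). Myh8 (-1.47), Chrna1 and Acta1 were called among 10 genes, 9 were lower over the list alone, and Myh3, embryonic myosin, was at -1.99 (adjusted p = 0.0563). Its medians on arrays 1 and 2 were -1.78 and -0.55. The erythroid list fell, with a median of -0.41 (adjusted p = 1.36e-05), and the endothelial list rose, with a median of 0.26 (adjusted p = 1.22e-05); each had an adjusted p = 0.580 with an estimated correlation. The erythroid medians on arrays 1 and 2 were -0.18 and -0.40, with 0 of 13 genes called and 4 lower over the list alone. The endothelial medians were 0.37 and 0.14, with 0 of 14 genes called over all genes or over the list alone.

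At the preset correlation no shift passed camera for macrophage genes (median 0.11, adjusted p = 0.147), which passed on ranks (0.0439) with medians of 0.32 and -0.12 on the 2 arrays, nor for cartilage (0.08, 0.504), dissection stress (0.13, 0.256) or gonad and Wolffian duct (-0.06, 0.256). Lhx9, a gonadal transcription factor gene, fell by 0.91 ± 0.00 on the log2 scale (adjusted p = 0.0398), with the Tbx2-GOF channel above background on 1 of 2 arrays; it was the 1 call among these 4 lists, over all genes and over each list alone. Its other kept probes were at -0.44 and -0.71, and over the alternatives Lhx9 ranged from -1.59 to -0.69. Among lists that did not pass camera, the medians of T-box factors, urothelium and dissection stress lay above the central 95% of random lists (percentiles 98.3, 99.8 and 97.9), and those of the hedgehog list and the ureteric mesenchyme transcription factors below it (0.11 and 0). In all, 12 of the 27 lists passed camera at the preset correlation, 6 upward and 6 downward, and 0 with an estimated correlation. The estimate leaves 1 degree of freedom with 2 arrays, so it could hardly call any list. Its lowest unadjusted p by camera was 0.0984, for the fibroblast and adventitia list. The preset of 0.01 treats the genes of a list as nearly independent, so its small p-values rest on genes and not on replicates.

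**Figure D3:**
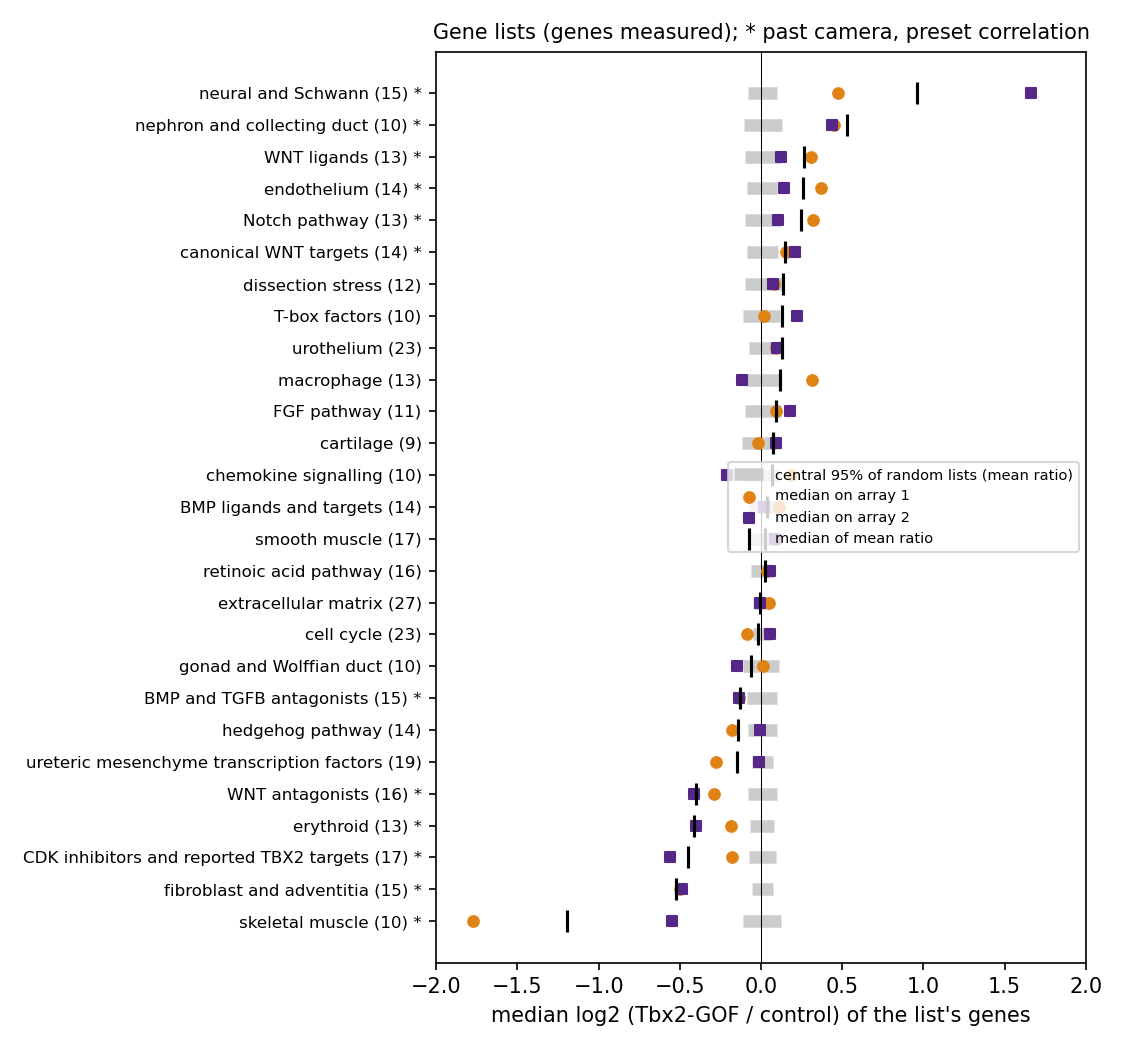
Median log2 ratio of Tbx2-GOF over control (x axis) of each of the 27 gene lists (y axis, genes measured in brackets) on array 1 (circles), array 2 (squares) and for the mean of both (black ticks); grey bars span the central 95% of 10000 random lists matched on intensity, and asterisks mark lists past camera at the preset correlation. The neural list lies at 0.48 and 1.66 and the skeletal muscle list at -1.78 and -0.55 on the 2 arrays, the widest gaps among the 27.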

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

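Every alternative below was listed beforehand except those named as added. The counts of called genes moved most: 0 in total, 0 risen and 0 fallen with the software's processed signals, with median centring and with the series value table, and 4 (2 and 2) with the separate-channel model. Scaling between arrays gave 330 (209 and 121), no filter on dim probes 276 (167 and 109) and the mean of a gene's probes 211 (124 risen). The estimated prior degrees of freedom were 3.65, 3.80 and 3.86 in the settings with 0 calls, 6.36 as reported and 8.37 with scaling; the cause was not tested. The other settings shared 135 calls of 158 (no background correction), 89 of 109 (offset 0), 122 of 142 (strict filter) and 125 of 171 (trend and robust estimation) with those reported. Of 42 named genes past the test, 42 kept their call with scaling, 26 with offset 0, 4 with the separate-channel model and 0 in the settings without calls. Among 1337 values of named genes in the settings that used both arrays, 0 changed sign. Named genes short of the threshold passed it in 39 of those values, among them Myh3 in 5 settings and Col4a1 and Upk2 in 4 each. These settings reprocess the same 2 arrays, so a stable sign is a weak check. On each array alone, some named genes not called differed in sign, such as Tbx3 (-0.03 and 0.39 on arrays 1 and 2) and Dhh (0.77 and -0.02). Tbx2 and Tbx18 stayed short of the threshold throughout. Genes at least 1.5-fold apart in the same direction numbered 543 with processed signals (89 opposite), 474 with the series table (68 opposite) and 57 at 2-fold; on 1 array alone, 752 to 1230 genes were beyond 1.5-fold. The correlation of the arrays fell to 0.0502 with median centring and otherwise lay between 0.251 and 0.343. For gene lists, 0 passed with an estimated correlation, each called list having an adjusted p of 0.580, which leaves 1 degree of freedom; 11 to 13 passed under each other alternative. BMP and TGFB antagonists missed the threshold with offset 0 (0.0573), processed signals (0.0618), median centring (0.0562), the series table (0.0554) and ranks (0.0675), and WNT ligands on ranks (0.135). Macrophage genes passed on ranks (0.0439), and ureteric mesenchyme transcription factors with median centring (0.0487), scaling (0.0382) and no dim filter (0.0415). The direction of the extracellular matrix list, not called in any setting, reversed with median centring (0.933) and on ranks (0.837); the cause was not tested. Added after seeing the data, leaving out 98 genes of muscle, neural, liver and adrenal lists gave 101 calls (59 and 42) and 269 genes at 1.5-fold. The liver and adrenal lists had been drawn up without the leading genes, so Afp, Alb, Serpina6, Ahsg and Akr1b7 were not left out. That count therefore does not show how many calls remain without the genes of these tissues. Also added after seeing the data, 101 calls (61 and 40) came from genes whose arrays differed by under 0.5. The ratio within each array already pairs 1 Tbx2-GOF with 1 control extract. Calls on 1 array alone were not possible because no residual degree of freedom is left. Signal over background limits what dim genes show: none of the genes added without the dim filter brought the 1.5-fold count above 289.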

Other observations

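Liver genes beyond the leading falls were examined with a list drawn up after those falls had been seen and without them. Of 15 measured genes 5 had a Tbx2-GOF channel not well above background on either array; such genes are kept through the control channel alone, which favours lower values. Of the 9 above background in both groups on both arrays 7 were lower on both, with a median of -0.36 (-0.33 and -0.40 on arrays 1 and 2). Past limma's test were Ambp at -1.03 ± 0.10 (adjusted p = 0.0307) and Ttr, the thyroid hormone carrier transthyretin, at -1.11 ± 0.32 (0.0379), whose Tbx2-GOF channel was above background on 1 of 2 arrays. A nephron progenitor list without Six2 had 0 of 11 genes called and 5 higher on both arrays; its median of 0.12 (-0.01 and 0.08 on the 2 arrays) lay just above the central 95% of random lists (-0.10 to 0.11). A Schwann cell list had a median of 0.45 with 0 of 10 called, although 9 of the 10 were higher on both arrays and the median lay above the central 95% of random lists (-0.11 to 0.14). Xist, the transcript of the inactive X chromosome, was at least 2.19-fold higher in Tbx2-GOF by the mean of the arrays and did not pass the test (adjusted p = 0.0701), with the control channel not well above background on either array, although the labels call the embryos male. The median of 4 Y-linked genes was -0.13, with 0 called, and Ddx3y was at -0.29.

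Of the tests below, the one on muscle tissue bringing in TBX2 targets, the one on the sign share of those targets and the ones on GC content were set before their results were seen; the others were set after. The first pattern is the lower level of skeletal muscle genes. A dye effect alone would give opposite signs on the turned arrays, but 90% of the list was lower on both. Smooth muscle genes, which have a median of 0.027, did not carry the change. A dye effect that follows probe GC content and intensity also left the difference between arrays in place, at -1.01 after that trend was removed against -1.08 before. A candidate explanation is skeletal muscle tissue in the extracts, unequal between the arrays: in a second muscle list the median was -0.49 and the array difference -0.37, below the central 95% of random lists (-0.17 to 0.17), as for the bright Myl4 (-2.45 and -0.53) and Tnni1 (-1.12 and -0.18), although Jsrp1 (0.17 and 0.00), Actn3 (0.14 and -0.07) and Smyd1 (-0.02 and -0.22) did not follow. Array and dye orientation cannot be separated, so a dye effect on these genes outside the GC and intensity trend could also make the arrays unequal. The array difference therefore does not decide for unequal tissue. Whether the genotype alters how much muscle stays attached stays open.

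The second pattern is the higher level of neural genes. Against a dye effect alone, 93.3% of the list was higher on both arrays. After the GC and intensity trend was removed the array difference was still -0.68, outside the -0.14 to 0.20 of random lists. Adrenal cortex beside the nerve tissue would raise steroidogenic genes. The median of 11 such genes was 0.0022, although Akr1b7 and the ACTH receptor gene Mc2r rose (3.27 and 1.27). Of the 11, Star, Cyp11a1, Nr0b1, Cyp11b1, Hsd3b1 and Cyp21a1 were dim, at mean log2 intensities from 7.23 to 7.93. The brighter Fdx1, Scarb1, Soat1 and Fdxr were at -0.03, 0.02, 0.14 and 0.14. The offset of 50 pulls ratios of dim probes toward 0, so the median does not exclude adrenal cortex. Nerve or ganglion tissue in the extracts, unequal between the arrays, may account for it: 19 of 20 sympathetic neuron genes, of which Dbh and Stmn2 are also in the first list, were higher on both arrays with a median of 0.92 and an array difference of -1.04, as for Npy at 0.41 and 1.73. Here too a dye effect outside that trend could make the arrays unequal, so the array difference does not decide for unequal tissue. More nerve tissue in the Tbx2-GOF ureter itself is not excluded.

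The third pattern is the lower level of reported TBX2 targets. If muscle tissue in the control extracts made the muscle genes unequal between the arrays, it would make this fall larger on array 1. The array difference had the other sign (0.28). Fewer matrix-producing cells would lower the extracellular matrix list about as much as the targets. Its median was -0.0051 (95% bootstrap interval over genes -0.13 to 0.10), so matrix genes as a set did not fall that far. Its members went both ways (9 higher and 8 lower on both arrays). The fibroblast and adventitia list, which shares Dkk2 with the targets, had a median of -0.52, so a part played by fewer cells of that kind stays open. A dye effect shared by the arrays cancels in the mean. Of the list, 64.7% had the same sign on both arrays, against 51.2% of all genes. The list's share lay between the 60% and 80% set beforehand as bounds, which alone did not decide. In a test added afterwards the list medians were -0.18 and -0.56 on arrays 1 and 2. Both lay under the central 95% of random lists (-0.10 to 0.10 and -0.12 to 0.14), where a dye effect alone needs opposite signs. No biological explanation was tested. The single Tbx2 probe, at 0.04 on array 1 and 0.56 on array 2, may lie outside the part of Tbx2 that the Hprt allele carries. Tbx2-GOF embryos also have only 1 normal Tbx18 allele, and part of the list was perhaps chosen on these samples.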
